A study of Homo sapiens with 24 samples.

How the data were processed

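Polyadenylated RNA was sequenced from HEK293T cells, a human embryonic kidney line that is easily transfected. Per the labels' protocols, cells were transfected with a lipid reagent, total RNA was selected on oligo-dT beads and treated with DNase, and libraries were made with the NEBNext Ultra RNA kit. The 24 libraries form 12 groups of 2. Each group combines 1 of 3 targets (ACTC1, MIAT or HBG1/2, here called the 3 series) with dCas9-VPR and a guide of 20, 16 or 14 nt, or with a control titled as a guide control. The tags of those controls state no transfection, so the titles and the tags disagree on what the controls received, and they are called guide controls here only by title. Groups were taken from the labels. No label says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

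Each library came with 1 table of gene-level estimates. Per the submitters' processing notes, the authors used RSEM 1.2.1 and the hg19 build. The aligner settings, the annotation release and the strand setting are not given in the sources used here. The deposited expected counts are RSEM's estimates of reads per gene and need not be whole, and 18.5% of them were fractional. The authors' TPM values divide those estimates by effective transcript length and sum to a fixed total in each library. The deposited FPKM values are the same estimates per transcript length and library size, and were not used in any test. RSEM divides a read that matches several genes among them, so values of near-identical genes are uncertain where their counts are fractional.

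The tables list 29889 gene models by cluster number and UCSC transcript identifiers, and the files used here do not pair them with names. A RefSeq table matched 6 of them by synonym, of which 1 passed the filter on counts, and none of these is reported as changed. ACTC1, MIAT, HBG1 and HBG2 were therefore not looked up, and the planned tests of target genes and of gene lists were not run. The rule fixed for naming genes took those with the largest absolute log2 fold change among called genes with a mean of at least 1 CPM. Because the models carry no names, at most 2 identifiers that rose and 2 that fell are printed here, and other gene models are described without one. Those described in the text were chosen after the results had been seen. No coordinates are given.

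Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 14056. Libraries were scaled with TMM factors. A quasi-likelihood model (estimateDisp, glmQLFit, glmQLFTest) was fitted to the 12 group means over all 24 libraries with 12 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison. A gene was called at an adjusted p under 0.05. The comparisons were each guide length against the guide control of its series, the 3 lengths jointly within a series, the mean of the lengths against the control in 1 series beyond the same difference in the other series, all dCas9-VPR groups against all controls, length averaged over the targets, and the 3 controls against each other. The mean of the 3 lengths against the control of each series was added later. CPM values scale counts to a common library total with TMM factors and are given as mean ± SD over 2 libraries. Where both control libraries held 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the group, which covers counting error only.

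Total expected counts ran from 4157128 to 6168361 in the ACTC1 series, from 4011869 to 7085299 in the MIAT series and from 1055828 to 2275878 in the HBG series. The edgeR step was tested on counts simulated for the 14056 genes from the real means and library sizes. For ACTC1 20 nt against its control it recovered 35.8% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 83.3% of those changed 4-fold. For HBG 20 nt against its control it recovered 23.9%, 52.2% and 77.3% at the same folds. For dCas9-VPR against the controls it recovered 68.7%, 83.6% and 95.5%. False calls among the unchanged genes numbered 4, 8 and 7. In the target-specific tests of ACTC1, MIAT and HBG they numbered 16, 10 and 11 of 13456 unchanged genes. These simulations gave every series the same spread.

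Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, no filter beyond a total above 0, limma 3.58.1 on log2(TPM + 1) for genes with a mean TPM of at least 1, the replicate number as a block, each library left out in turn, a fit on the 8 libraries of a series alone, other control libraries, and an additive model of target and dCas9-VPR. Alternatives chosen after the data were seen were a fit without the HBG series, all libraries thinned to the total of the shallowest, and limma's voom with a weight per series. Counts of 2 replicates of a group differed by 2.18 to 3.66 times the chi-square value of sampling noise, so no library was treated as a copy of another.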

Results

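Gene expression was measured by polyA RNA sequencing in HEK293T cells given dCas9-VPR, a Cas9 without nuclease activity that is fused to a transcriptional activation domain and that a guide RNA brings to a chosen promoter. Guides of 20, 16 or 14 nt were directed at ACTC1, a cardiac actin gene, at MIAT, a long non-coding RNA gene, or at the fetal globin genes HBG1/2. The design asked what a shortened guide changes in the activation of its target and in the rest of the transcriptome. Each of the 9 combinations and each of the 3 matching guide controls had 2 libraries. Total expected counts per library ran from 4157128 to 6168361 in the ACTC1 series, from 4011869 to 7085299 in the MIAT series and from 1055828 to 2275878 in the HBG series. In each library 13594 to 16713 gene models had a count. The gap between annotated and effective length, which follows the fragment length RSEM estimated, was 39.6 to 57.7 bases in the HBG series against 61.4 to 79.2 bases in the other series.

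**Figure D1:**
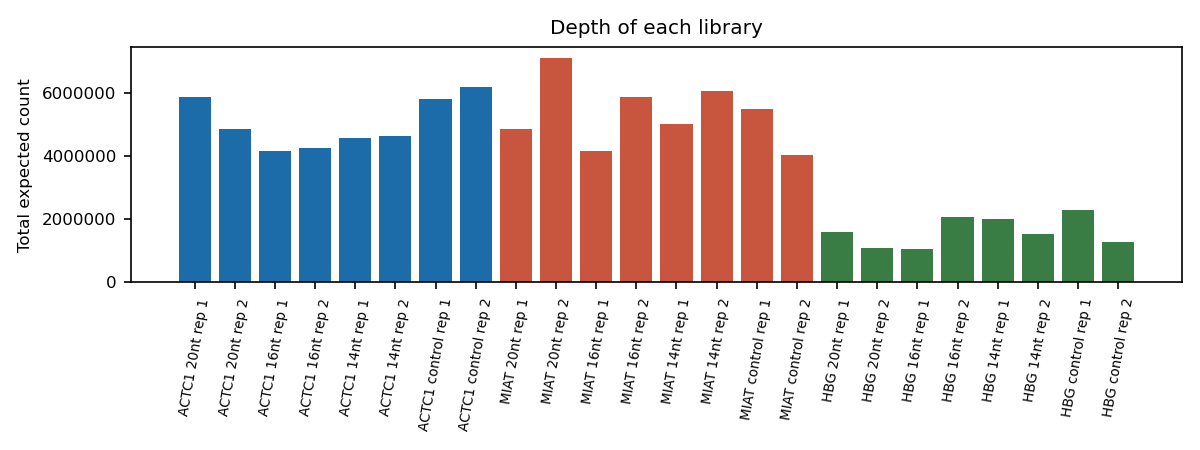
Total expected count of each library (vertical axis), coloured by series. The HBG libraries held 1055828 to 2275878, below all libraries of the other series.

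In the ACTC1 series the gene model uc001ziu.1 was not detected in the control and rose with dCas9-VPR at all guide lengths. It reached 40.4 ± 2.89 CPM (SD, n = 2) with the 20 nt guide, 12.01 ± 4.40 CPM with the 16 nt guide and 23.2 ± 4.10 CPM with the 14 nt guide. Against a floor of 3 counts over the control libraries it was at least 158-fold, 46.7-fold and 90.6-fold higher, with adjusted p = 5.7e-10, 5.1e-07 and 5.0e-09. Its expected counts were whole numbers in all 10 libraries that had any, which shows no sign of reads divided between genes. In the MIAT and HBG series it had at most 3 counts in a library. A different gene model of 7 transcripts was also at 0 counts in the ACTC1 control, and had 3.58 ± 0.71 CPM at 20 nt, 10.5 ± 3.87 CPM at 16 nt and 24.1 ± 1.65 CPM at 14 nt. It was at least 14.1-fold, 40.7-fold and 94.0-fold higher than the control (adjusted p = 0.0059, 9.7e-05 and 2.0e-06). Its difference between 14 and 20 nt was 2.73 ± 0.61 (log2, SE) and missed the threshold (adjusted p = 0.0768). The call at 20 nt was lost without 20 nt replicate 1 (adjusted p = 0.0713) and without control replicate 1 or 2 (adjusted p = 0.141 and 0.162). The gene model uc003ydk.2 fell by 0.48 ± 0.08 (log2, SE) at 20 nt, by 0.51 ± 0.08 at 16 nt and by 0.64 ± 0.08 at 14 nt, from 694 ± 3.19 CPM in the control (adjusted p = 3.8e-04, 2.0e-04 and 1.5e-06). Its expected counts were fractional in 11 of the 24 libraries. Its fall at 20 nt ended as a call without 20 nt replicate 2 (adjusted p = 0.0636), and against the mean of the 3 control groups no fall of it passed the threshold (adjusted p = 0.816, 0.651 and 0.0799).

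Over all tested genes, 21 were higher and 14 lower with the 20 nt ACTC1 guide, 23 higher and 6 lower with the 16 nt guide, and 66 higher and 14 lower with the 14 nt guide. Genes that rose did so by more than those that fell: the median log2 fold change of higher genes was 2.79, 2.50 and 1.45 for the 3 lengths, and of lower genes -0.32, -0.33 and -0.36. The higher genes include some at 0 counts in the control, whose fitted folds have no upper limit; with such genes at the fold from 3 counts over the group, every median given here and for the other targets was the same. Of the 35, 29 and 80 calls, 14 genes were higher and 3 lower at every length. Calls fell to 17, 14 and 19 for 20 nt without 20 nt replicate 1, 20 nt replicate 2 or control replicate 2, to 12 and 14 for 16 nt without 16 nt replicate 2 or control replicate 2, and to 36 to 52 for 14 nt without any 1 of its 4 libraries. A fit on the 8 libraries of the series alone called 146, 122 and 226. More genes were higher than lower at 14 nt in every setting, but not at 20 nt. There the series alone had 57 higher and 89 lower, DESeq2 29 and 94, and voom 42 and 61. DESeq2 gave adjusted p-values to only 1786 genes in that comparison, against 14056 tested with edgeR, so its balance leaves out most of them. Thinning to equal depth gave 10 and 10 at 20 nt. At 16 nt the series alone had 61 and 61. Against the mean of the 3 control groups there were 155 and 155 at 20 nt and 146 and 147 at 16 nt. Without control replicate 1 there were 13 and 13 at 20 nt.

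**Figure D2:**
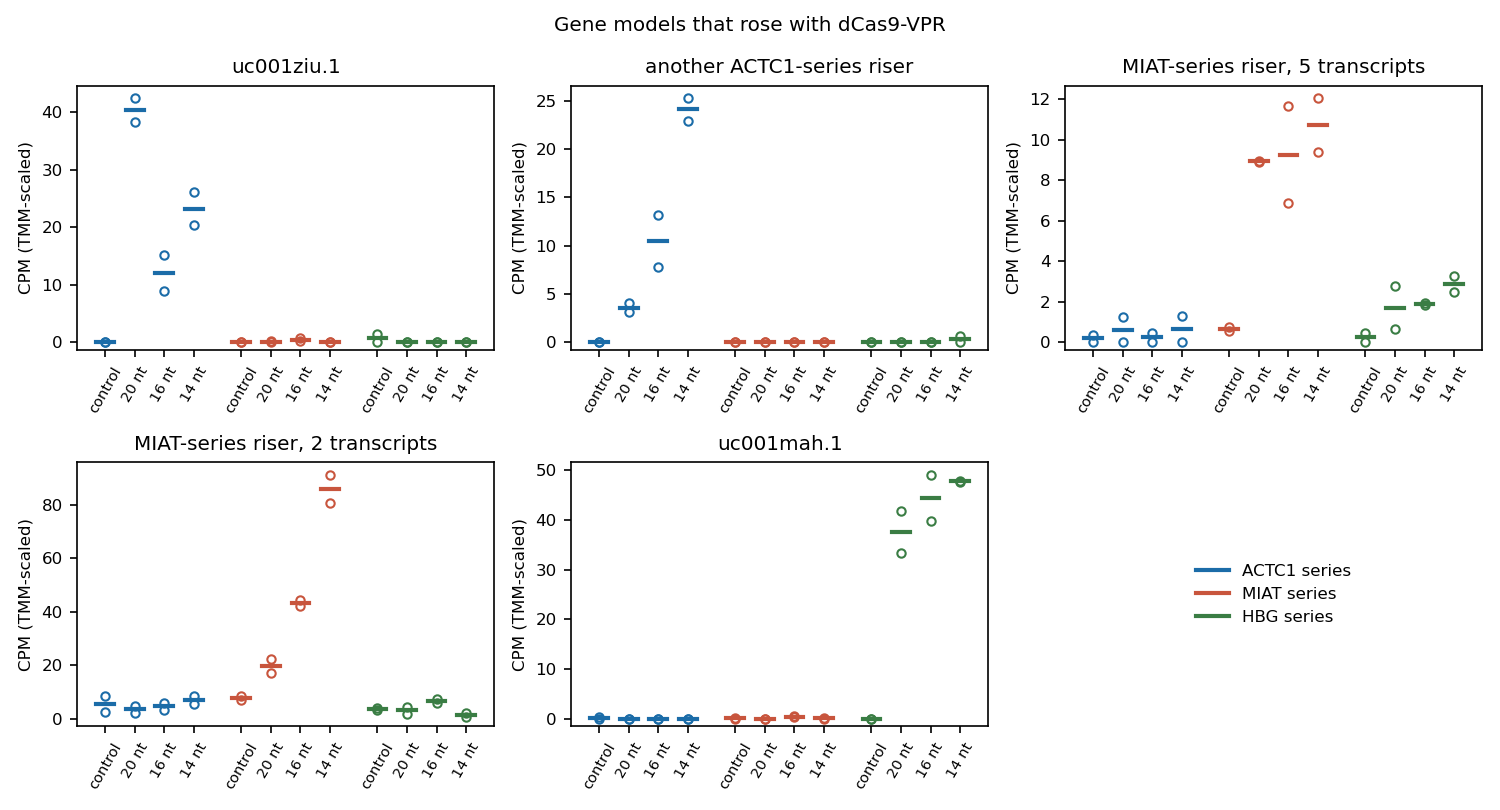
Expression in CPM (TMM-scaled, linear axis) of 5 gene models that rose with dCas9-VPR, in each of the 12 groups. Open circles are the 2 libraries of a group and bars their mean. uc001ziu.1 was highest with the 20 nt ACTC1 guide (40.4 CPM), whereas another ACTC1-series riser and the MIAT-series riser of 2 transcripts were highest with the 14 nt guide (24.1 and 86.2 CPM). The MIAT-series riser of 5 transcripts had 8.93 to 10.7 CPM over the 3 lengths.

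In the MIAT series few genes rose. The largest called rise was that of a gene model of 5 transcripts, from 0.66 ± 0.13 CPM in the control (3 counts in each library) to 8.93 ± 0.038 CPM at 20 nt, 9.27 ± 3.37 CPM at 16 nt and 10.7 ± 1.88 CPM at 14 nt. Its log2 fold change was 3.71 ± 0.85 (SE), 3.75 ± 0.85 and 3.97 ± 0.85, of which only that at 14 nt passed the threshold (adjusted p = 0.0931, 0.0562 and 0.0269). That call was lost without any 1 of its 4 libraries (adjusted p from 0.0666 to 0.621), and the expected counts were fractional in 4 of the 19 libraries that had any. Its mean was also higher with dCas9-VPR in the HBG series, at few counts. There it had 0.23 CPM in the control and 1.70, 1.89 and 2.88 CPM at 20, 16 and 14 nt. In the ACTC1 series it had at most 0.65 CPM in a group mean. A different riser, a gene model of 2 transcripts with whole counts in all 24 libraries, increased from 7.60 ± 1.08 CPM in the control to 19.6 ± 3.60 CPM at 20 nt, 43.1 ± 1.58 CPM at 16 nt and 86.2 ± 7.44 CPM at 14 nt. The log2 fold change was 1.39 ± 0.33 (SE) at 20 nt, which did not pass the threshold (adjusted p = 0.123), 2.51 ± 0.32 at 16 nt (adjusted p = 1.1e-05) and 3.51 ± 0.31 at 14 nt (adjusted p = 1.9e-09). In the other series it lay between 1.32 and 6.95 CPM in every group mean. The gene model uc001bps.3 fell from 152 ± 42.0 CPM in the control to 79.3 ± 6.20 CPM at 20 nt, 68.4 ± 3.15 CPM at 16 nt and 95.9 ± 21.6 CPM at 14 nt. Its expected counts were fractional in 5 of the 24 libraries. The log2 fold change was -0.93 ± 0.14, -1.14 ± 0.14 and -0.65 ± 0.14 (adjusted p = 3.5e-04, 1.1e-05 and 0.0269). Without control replicate 2 the falls at 20 and 14 nt lost the threshold (adjusted p = 0.165 and 0.841), as did the fall at 20 nt without 20 nt replicate 2 (adjusted p = 0.0614) and at 14 nt without 14 nt replicate 1 (adjusted p = 0.561).

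The 20 nt MIAT guide had 1 gene higher and 12 lower, the 16 nt guide 3 higher and 17 lower, and the 14 nt guide 5 higher and 19 lower. The median log2 fold change of the lower genes was -0.59, -0.54 and -0.53. One gene was higher and 7 were lower at every length. The 20 nt count fell from 13 to 6, 5 and 5 without 20 nt replicate 1, 20 nt replicate 2 or control replicate 2. The 16 nt count fell from 20 to 6, 8 and 9 without 16 nt replicate 1, 16 nt replicate 2 or control replicate 2. The 14 nt count fell from 24 to 10, 13 and 9 without 14 nt replicate 2, control replicate 1 or control replicate 2. The series fitted alone gave 33, 63 and 59 calls. The excess of lower genes depended on 1 library and was absent in 1 other setting: without control replicate 2 there were 3 higher and 2 lower at 20 nt and 4 and 5 at both 16 and 14 nt, and limma on log2(TPM + 1) gave 1 and 1, 1 and 0, and 5 and 1.

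In the HBG series the gene model uc001mah.1, a cluster of 4 transcripts, was at 0 counts in both control libraries and rose with all 3 guide lengths. It reached 37.6 ± 6.04 CPM at 20 nt, 44.5 ± 6.58 CPM at 16 nt and 47.8 ± 0.083 CPM at 14 nt. These levels were at least 44.1-fold, 52.7-fold and 54.8-fold higher than the control (adjusted p = 5.7e-06, 2.7e-06 and 2.4e-06). The difference between 14 and 20 nt was 0.34 ± 0.46 (log2, SE; adjusted p = 0.828) and that between 16 and 20 nt 0.24 ± 0.46 (adjusted p = 0.870), so a difference by length was not detectable at this depth. It had at most 2 counts in any library of the other series, and its counts were whole in the 11 libraries that had any.

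The HBG series had the most calls in the fit over all libraries, with 127 genes higher and 202 lower at 20 nt, 88 higher and 154 lower at 16 nt, and 97 higher and 118 lower at 14 nt. Higher genes had a median log2 fold change of 1.062, 1.110 and 1.077 and lower genes of -0.53, -0.47 and -0.51. At every length 19 genes were higher and 45 lower. These counts rest on a spread shared with the other series: fitted on its own 8 libraries, the HBG series gave 63, 68 and 57 calls, fewer than the ACTC1 series. Its replicates also lay farther apart, with an SD of the log2 difference between replicates of 0.19 to 0.27 over genes of at least 100 CPM, against 0.10 to 0.13 in the other series. The highest SD was in the 20 nt group. This SD includes counting noise, which is larger in shallow libraries. Relative to the chi-square value of sampling noise the series overlapped, at 2.53 to 3.66 for HBG and 2.18 to 3.15 for the others. The common dispersion of each series alone was 0.0220 for HBG, 0.00815 for ACTC1 and 0.00476 for MIAT. Without control replicate 1 or 2 the counts were 137 and 114 at 20 nt, 101 and 63 at 16 nt, and 112 and 82 at 14 nt. The 16 nt count was 149 and 89 without 16 nt replicate 1 or 2, and the 14 nt count 106 without 14 nt replicate 1. On log2(TPM + 1) values limma gave another balance at 20 nt, with 503 genes higher and 244 lower.

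**Figure D3:**
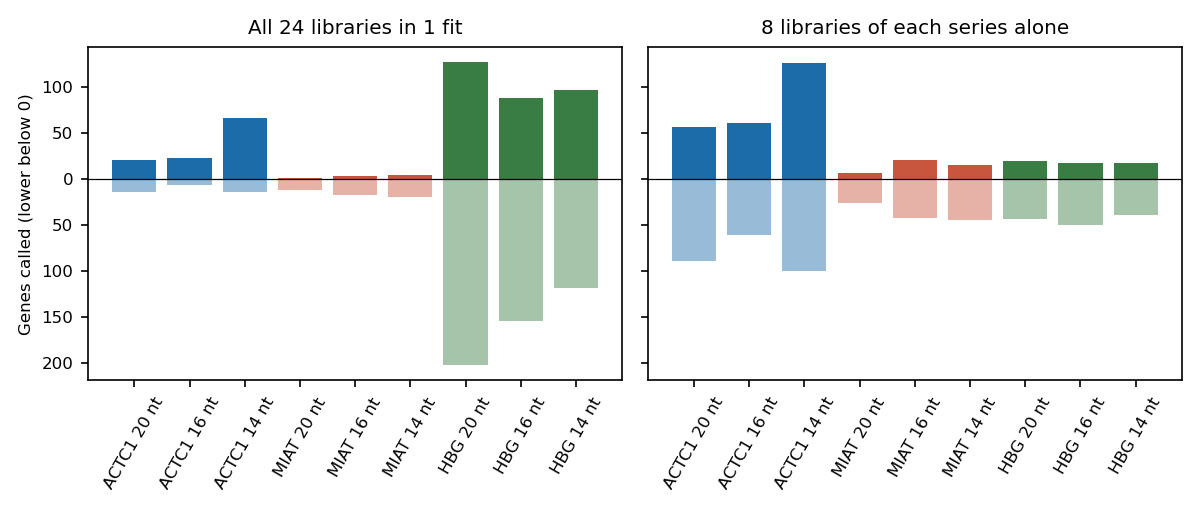
Number of genes called higher (solid, above 0) and lower (pale, below 0) than the guide control for each target and guide length, in the fit over all libraries (left) and in fits on each series alone (right). HBG 20 nt had 329 calls on the left and 63 on the right, and ACTC1 14 nt 80 and 226.

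Within a series, few genes differed between guide lengths in the edgeR fit over all libraries. In the ACTC1 series 15 genes did in the joint test, and 13 of them were highest with the 14 nt guide. A direct test of 14 against 20 nt called 12 genes, all 12 higher at 14 nt, whereas 16 against 20 nt called 1, which was lower. The gene model uc001ziu.1 was not among the 15 (adjusted p = 0.188), although its level at 16 nt was lower than at 20 nt by 1.75 ± 0.39 (log2, SE; adjusted p = 0.249). In the MIAT series 4 genes passed, among them the riser of 2 transcripts, which was 2.12 ± 0.27 (log2, SE) higher at 14 than at 20 nt (adjusted p = 3.4e-05). The riser of 5 transcripts was not among them: it differed by 0.27 ± 0.63 between 14 and 20 nt (adjusted p = 1.0). In the HBG series 12 genes passed, of which 6 were highest at 14 nt and 5 at 20 nt. That count depended on the setting: 345 with limma on log2(TPM + 1), 201 with DESeq2 and 145 without the low-count filter. It was 17 for the series alone and 0 with voom. Calls depended on single libraries: the HBG count was 0 without 16 nt replicate 2, 45 without 20 nt replicate 2, 29 without 14 nt replicate 2, and 7 without 20 nt or 14 nt replicate 1. The ACTC1 count was 4 to 8 without any 1 of its libraries other than 16 nt replicate 2 (12), and the MIAT count 9 without 14 nt replicate 1. Averaged over the targets, length changed 1 gene, by 0.17 at 16 nt and 1.47 at 14 nt (log2, adjusted p = 0.0181), with 1106 genes at an unadjusted p under 0.05. That gene passed the joint test in the ACTC1 series, with a change of 2.92 at 14 nt (adjusted p = 9.1e-07), and not in the MIAT or HBG series (0.16 and 1.34). That 1 call was lost without ACTC1 14 nt replicate 1 or 2, MIAT 14 nt replicate 2 or HBG 14 nt replicate 2.

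Changes with 1 target beyond those with the other targets were called for 13 genes in the ACTC1 series (9 higher, 4 lower), 12 in the MIAT series (2 higher, 10 lower) and 80 in the HBG series (37 higher, 43 lower). The test subtracts the mean change in the other series, so a call can also come from a change there. A gene model called lower for MIAT by 3.61 (log2) had 2.15 CPM in the MIAT control and 0.91 to 2.05 CPM with dCas9-VPR. In the ACTC1 series it rose from 1.09 CPM to between 10.1 and 53.9 CPM. On simulated counts, where some genes were truly changed, the target-specific test gave 16, 10 and 11 false calls for the 3 series. The simulation changed 67, 67 and 66 genes by 1.5-, 2- and 4-fold in each series. False calls at a fixed adjusted p rise with the number of calls, so these counts do not carry over to the real lists. The HBG balance was 69 higher and 28 lower with limma on log2(TPM + 1), 5 and 23 with voom, and 9 and 30 at equal depth. The MIAT balance was 21 and 21 without the low-count filter and 9 and 10 with voom. The change of the MIAT-series riser of 2 transcripts was 2.70 ± 0.48 (log2, SE) higher than in the other series (adjusted p = 0.0041). That of uc001bps.3 was 1.12 ± 0.14 lower than there (adjusted p = 2.5e-05). Its mean rose in those series, from 87.4 CPM in the ACTC1 control to between 95.8 and 105 CPM. In the HBG series it rose from 130 CPM to between 142 and 166 CPM. Both calls were lost with limma on log2(TPM + 1). The riser of 5 transcripts did not pass (1.85 ± 1.64, adjusted p = 0.922). In the HBG series uc001mah.1 passed this test (adjusted p = 0.0199). uc001ziu.1 did not (adjusted p = 1.0). It was at 0 counts in the MIAT control as well as the ACTC1 control, which leaves its contrast without a usable error. In the ACTC1 and MIAT controls uc001mah.1 had 2 and 1 counts, each in 1 library, and its pass rests on these. The ACTC1 count was 6 or 7 without ACTC1 20, 16 or 14 nt replicate 2, ACTC1 control replicate 2, MIAT control replicate 2 or HBG control replicate 1, and 23 without HBG 20 nt replicate 2. The MIAT count was 5 and 7 without MIAT control replicate 1 or 2. The HBG count was 21 and 12 without HBG control replicate 1 or 2, 35 without ACTC1 control replicate 1, 49 without MIAT control replicate 1, and 133 without HBG 20 nt replicate 1.

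Over all targets and lengths, 702 genes differed between the dCas9-VPR libraries and the guide controls, 223 higher and 479 lower. The changes were small: the median log2 fold change was 0.40 for higher and -0.21 for lower genes, and 22 genes rose and 8 fell at least 2-fold (21 and 5 with groups at 0 counts taken as 3 counts). Lower genes were abundant, with a median of 213 CPM against 44.5 CPM for higher genes and 27.6 CPM for all tested genes. In all 9 separate comparisons 138 of the higher and 348 of the lower genes kept their sign. The pooled comparison is the average of these 9, which share the 3 controls, so this agreement is partly built in. The gene model uc003ydk.2 fell by 0.32 ± 0.04 (log2, SE; adjusted p = 9.7e-07) and had a lower sign in all 9. In the HBG series its libraries overlapped those of the control. It had 308 ± 25.7 CPM in that control against 281 ± 51.7 CPM at 20 nt, 301 ± 14.4 CPM at 16 nt and 291 ± 30.2 CPM at 14 nt. The balance was another with limma on log2(TPM + 1), which called 372 higher and 76 lower and differs in its model, filter and scaling. There the median log2 fold change over its tested genes was 0.08, against -4.6e-05 in the edgeR fit. TMM factors, which TPM values do not use, were 0.964 to 0.985 in the control libraries and 0.992 to 1.032 in the dCas9-VPR libraries. Whether the scaling accounts for the other balance was not tested. With RLE factors 229 were higher and 443 lower. Without ACTC1 control replicate 2, MIAT control replicate 1 or HBG control replicate 1 the count was 424, 428 and 434.

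The 3 guide controls differed from each other in 2902 genes, so target and any batch cannot be told apart in a comparison across series. Without the HBG series, 605 genes differed between the ACTC1 and MIAT controls, 289 higher and 316 lower in the MIAT control. Without HBG control replicate 1 the count over the 3 controls was 1672.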

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

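The tests of depth and of a shared spread were chosen after the HBG counts had been seen. The test of the size of the changes and the relabelings of libraries were set before their results.

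The difference between the series was itself tested, and genes passed it in each: 13 in the ACTC1 series, 12 in the MIAT series and 80 in the HBG series. Libraries were relabelled at random within each series, and 100 labelings were counted with the real one included. As many genes as the real 12 of the MIAT series came from 1 labeling, the real one, and the highest other gave 7. The labelings mixed controls with dCas9-VPR libraries, so they test only whether the libraries of a series are interchangeable. A change shared by all targets breaks that too, so chance is not excluded for a target-specific difference. For the HBG series 3 labelings gave at least 80 genes, with 256 as the highest other. A labeling that calls several times the real count points to a structure of the samples, so chance is not excluded there either. For the ACTC1 series 7 labelings gave at least 13 genes, with 104 as the highest other, and chance cannot be excluded.

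The gene models behind the text that passed this test were uc001mah.1 in the HBG series (adjusted p = 0.0199), and uc001bps.3 and the riser of 2 transcripts in the MIAT series (adjusted p = 2.5e-05 and 0.0041). The call of uc001mah.1 was lost without HBG control replicate 1 or 2 (adjusted p = 0.0620 and 0.0595). It was also lost without ACTC1 control replicate 2 or MIAT control replicate 1, where a group is left at 0 counts and the contrast has no usable error (adjusted p = 1.0). The call of that riser was lost without MIAT control replicate 1 (adjusted p = 0.0806) or HBG control replicate 1 (adjusted p = 0.279).

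More genes were called in the HBG series than in the others: the mean of the 3 lengths differed from the control in 467 genes, against 100 in the ACTC1 and 55 in the MIAT series. Without control replicate 1 or 2 of the same series the counts were 197 and 151 for HBG, 40 and 23 for ACTC1, and 19 and 18 for MIAT. In the order ACTC1, MIAT and HBG, voom gave 246, 249 and 137, which reverses the order, at series weights of 0.92, 1.15 and 0.94. The HBG weight was not below the ACTC1 weight, so the weights alone do not explain that reversal. Equal depth gave 24, 24 and 315. Greater depth as the source is argued against, since the highest HBG total was 0.55 times the lowest ACTC1 total. Whether low depth widened the spread was not tested. A spread shared by all series may account for the excess: the common dispersion was 0.0220 in the HBG series alone and 0.00846 over all libraries, and with each series fitted alone the HBG count was 0.49 times the ACTC1 count (135 and 275). Larger changes with the HBG guides stay open too, since the covariance over 2276 abundant genes between changes from disjoint libraries was 2.42 and 2.57 times that of the ACTC1 series in the 2 pairings. A batch that parts the HBG control libraries from its dCas9-VPR libraries would raise that covariance as well, and the labels give no batch with which to separate it.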

How the results depend on the processing

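Counts of called genes are given in the order 20, 16 and 14 nt. RLE factors and the replicate number as a block left all 18 counts within 1.5 times, for example 672 and 648 in place of 702 for dCas9-VPR against the controls. No strong pairing by replicate number was seen, since deviations of same-numbered libraries correlated by -0.091 to 0.106 over genes. Noise of single libraries lowers such correlations, so a weak pairing is not excluded. The additive model gave 505, and a fit without the HBG series gave 529 for that comparison. Of the 24 calls followed for gene models described in the text, none changed sign under any setting. RLE, DESeq2, no filter, the series alone and voom lost none that they tested. limma on TPM lost 9: uc003ydk.2 at ACTC1 20 and 16 nt and MIAT 16 nt, uc001bps.3 at all 3 MIAT lengths and in the target-specific test, and the MIAT-series riser of 2 transcripts at 16 nt and in that test. Thinning lost 9: uc001ziu.1 at 16 nt, the other ACTC1-series riser at 20 and 16 nt, uc003ydk.2 at the 3 lengths just given, uc001mah.1 in the target-specific test, and the MIAT-series riser of 5 transcripts at 14 nt and over all targets. Other controls lost 5: uc003ydk.2 at all 3 ACTC1 lengths and MIAT 16 nt, and uc001bps.3 at 14 nt. The block lost the riser of 5 transcripts at 14 nt. Leaving out 1 library lost the call in 26 of 196 tests. Causes of the following shifts were not tested, except that thinning has fewer counts and the series alone have other spreads.

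Without the low-count filter the ACTC1 counts were 87, 97 and 150, the MIAT counts 34, 54 and 69, and HBG 14 nt 341. Length counts were 55 (ACTC1), 36 (MIAT), 145 (HBG) and 69 (over targets), and target-specific counts 52, 42 and 174 (ACTC1, MIAT, HBG). DESeq2 gave 123 (29 higher, 94 lower), 76 and 146 for ACTC1, 82, 78 and 137 for MIAT, and 515, 430 and 374 for HBG. It gave 28 (ACTC1), 201 (HBG) and 14 (over targets) for length and 55, 28 and 206 for the target-specific tests. Only 1786 genes had a DESeq2 adjusted p for ACTC1 20 nt, and 1006, 2175 and 1396 for the MIAT lengths. limma on log2(TPM + 1) gave 13, 16 and 33 for ACTC1, 2, 1 and 6 for MIAT, and 747, 689 and 386 for HBG. It gave 3, 0 and 345 for length in ACTC1, MIAT and HBG, 2 for the MIAT-specific test and 448 (372 higher, 76 lower) for dCas9-VPR. Its HBG splits were 503 higher and 244 lower, 540 and 149, and 295 and 91. Its MIAT splits were 1 higher and 1 lower, 1 and 0, and 5 and 1. voom gave 103 (42 higher, 61 lower), 64 and 170 for ACTC1, 103, 95 and 209 for MIAT, and 42, 54 and 41 for HBG. It gave 30, 18 and 0 for length, 0 over targets, and 19 (MIAT) and 28 (HBG) for the target-specific tests.

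Each series alone gave 146 (57 higher, 89 lower), 122 and 226 for ACTC1, 33, 63 and 59 for MIAT, 63, 68 and 57 for HBG, and 45 (ACTC1) and 12 (MIAT) for length. Against the mean of all controls the counts were 310, 293 and 462, then 767, 1010 and 660, then 2109, 1900 and 1761. Target-specific tests without controls gave 1982, 5157 and 5604, so these hold the differences between series. At equal depth (1055803 counts) they were 20, 6 and 26, then 8, 9 and 15, then 211 (20 nt) and 112 (14 nt) for HBG. Length gave 3 (ACTC1), 25 (HBG) and 0 (over targets), the target-specific tests 7, 7 and 39, dCas9-VPR 284 and the controls 1633. Without the HBG series length over targets gave 8, and the controls 605. Of the counts of 0, limma's for MIAT length had 120 genes at an unadjusted p under 0.05, voom's for HBG length 734 and over targets 901, and edgeR's over targets at equal depth 775.

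Leaving out each library in turn gave 14 to 26, 12 to 24 and 36 to 52 for ACTC1, 5 to 13, 6 to 19 and 9 to 16 for MIAT, and 114 to 339, 63 to 149 and 82 to 158 for HBG. Length gave 4 to 12 (ACTC1), 4 to 9 (MIAT), 0 to 45 (HBG) and 0 to 8 (over targets). Target-specific counts were 6 to 23, 5 to 17 and 12 to 133, dCas9-VPR 424 to 863 and the controls 1672 to 2562. A lone remaining library is assumed to vary like the other groups. The other settings meant for target genes and gene lists, including a sum over paralogs, were not run because the gene models have no names here. Depth limits the HBG series most, as the simulated recovery shows.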

Other observations

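The test of a single library and that of depth for the 14 nt ACTC1 guide were chosen after the counts had been seen.

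Genes called at 1 guide length were often called at another length of the same target, and no gene was called in opposite directions at 2 lengths. In the ACTC1 series 14 genes were higher and 5 lower at both 20 and 16 nt, where independent lists would share 0.034 and 0.0060. In the MIAT series 1 gene was higher and 10 lower at both of these lengths, with 0.00021 and 0.015 for independent lists. In the HBG series 34 were higher and 75 lower, with 0.80 and 2.21 for independent lists. Simulated groups without any change, set against the same controls, shared 0.1, 0.3 and 0 calls on average over 10 simulations. At 20 nt they had only 0.2, 1 and 0.2 calls on average. They could therefore share almost none, and do not measure how much of the real overlap comes from the shared control. These simulations used the spread fitted over all series, which is below that of the HBG series alone.

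The 3 series share no library, and changes with dCas9-VPR were compared between them as a hypothesis of a common effect. Of the 100 genes called for the mean of the lengths in the ACTC1 series, 84.0% (exact 95% binomial interval 75.3 to 90.6%) had the same sign in the MIAT series and 80 of them in the HBG series. Of the 55 called in the MIAT series 70.9% had the same sign in the ACTC1 series, the lowest of the 6 shares, and 81.8% in the HBG series. Of the 467 called in the HBG series 75.8% and 78.6% had the same sign in the ACTC1 and MIAT series. Over all tested genes 54.0 to 57.9% had the same sign, and genes are not independent, so the interval is too narrow. Genes called lower in the ACTC1 series had a median log2 change of -0.21 in the MIAT series and -0.19 in the HBG series, and genes called higher in the ACTC1 series one of 0.17 and 0.28. In all 6 pairs the share that agreed was larger among lower than among higher genes, which was not tested. For the ACTC1 series 37 and 35 of 39 lower genes agreed in the MIAT and HBG series, against 47 and 45 of 61 higher genes. For the MIAT series 34 and 41 of 47 lower genes agreed in the ACTC1 and HBG series, against 5 and 4 of 8 higher genes. For the HBG series 236 and 250 of 298 lower genes agreed in the ACTC1 and MIAT series, against 118 and 117 of 169 higher genes. These shares are consistent with a common part of the response. Whether it comes from dCas9-VPR or from transfection cannot be separated, since the labels leave open what the controls received. For the pooled comparison, 1 of 100 labelings within series, the real one, called as many as 702 genes and the highest other called 219. The labelings mixed controls with dCas9-VPR libraries, so they argue only against the libraries of a series being interchangeable. A difference between guide lengths or a batch would break that too, so chance is not excluded for a difference with dCas9-VPR. For guide length averaged over the targets 29 of 100 labelings called at least the 1 gene of the real one, with 13 as the highest other, and chance cannot be excluded.

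More genes were higher with the 14 nt ACTC1 guide (66) than with the 20 nt guide (21). A single library is argued against, since 36 or more genes were higher when either 14 nt library was left out. Greater depth is argued against, since the highest total of a 14 nt library was 0.95 times the lowest of a 20 nt library. An effect of guide length stays open as a hypothesis: in the direct test 12 genes differed and 100% of them were higher at 14 nt. The same test called 4 genes in the MIAT series, 2 of them higher at 14 nt, and 7 in the HBG series, 4 of them higher, and the excess itself was not tested between targets.

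In 41 of the calls against a control the gene was at 0 counts in both libraries of 1 side, which involved 29 gene models. Reads shared between near-identical genes may account for some of them: 55.2% had fractional expected counts in most of their libraries, against 32.3% of the other tested genes and 36.4% of genes matched on mean expression, whose upper 97.5% limit over 1000 draws was also 55.2%. The guide is the other explanation, and in 41.9% of the 31 gene and series pairs the control was at 0 counts and all 3 lengths at 1 CPM or more, or the reverse. The fractional share met the first bound set for it, on the share itself, but not the second, on its ratio to the other tested genes. The guide share did not reach its bound. Gene models with whole counts, such as uc001ziu.1 and uc001mah.1, show no sign of divided reads. Which of the fractional ones were called through divided reads cannot be told apart here.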
